A study of Homo sapiens with 8 samples.

How the data were processed

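The samples were MCF7 and MDA-MB-231 cultures given 1 µM all-trans retinoic acid or vehicle for 6 or 48 h. Per the labels, total RNA was extracted with a miRNeasy kit, labelled by amino allyl cDNA synthesis with Cy3 or Cy5 and hybridized to 2-colour Agilent 4x44K human arrays, design Agilent-014850. Each of the 8 arrays compared retinoic acid with vehicle within 1 line and time. The 4 groups had 2 biological replicates, with the dyes exchanged between them, so the replicate number and the dye orientation cannot be parted. The arrays had been scanned as 3 slides: slide 1 held MCF7 48 h replicates 1 and 2 and MCF7 6 h replicate 1, slide 2 held MDA-MB-231 48 h replicate 1 and 6 h replicates 1 and 2, and slide 3 held MCF7 6 h replicate 2 and MDA-MB-231 48 h replicate 2.

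Per the file headers, the authors' scans were read with Agilent Feature Extraction 9.1.3.1, protocol GE2-v5_91_0806. The deposited intensity values comprise the mean pixel signal of each spot, the median of its local background, and processed signals that the software had background-subtracted, spatially detrended and dye-normalized by a linear factor and lowess. The deposited log10 ratio, per the file headers, is the processed red over the processed green signal. The authors' value table holds log2 ratios of red over green, normalized within each array in a way not stated, and not turned for the dye swaps. On bright spots, the regression slope of the authors' ratios on the software's log2 ratio was 1.00 to 1.03 on 7 arrays and 0.67 on MCF7 6 h replicate 2. No genome build is named for the array, so no positions are given.

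Mean signals were background-corrected by normexp with an offset of 50, normalized within arrays by loess with 4 iterations, and turned so that every log2 ratio is retinoic acid over vehicle, in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Spots that the software had marked as outliers were removed, and replicate spots of a probe were averaged. A probe was kept if it was well above background in either channel on both arrays of at least 1 group, which left 32461 of 41000 probes. Each gene was represented by its brightest probe, which gave 23723 genes. Probes were named by sequence accession (23958), current symbol (2755) or synonym (1032) from a RefSeq gene table of assembly GRCh38.p14, used for names alone, and 13255 kept the name in the file.

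Retinoic acid was tested against vehicle by limma over all 8 arrays, with 1 coefficient per group and an empirical Bayes estimate of the spread shared by the groups. A gene measured on 1 array of a group is thus assumed to vary there as in the other groups. Each contrast and its error were solved for the arrays that a gene was measured on. The p-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 are called. Differences between lines at each time (MCF7 minus MDA-MB-231) and between times in each line (48 h minus 6 h) were contrasts of the same fit. Vehicle levels were compared between lines by limma on the vehicle channel of each array after normalization of mean signals across arrays (Aquantile), with time as a covariate. Some folds are given as at least a value, because the lower of the compared signals lay at background. They were computed from mean signals, against the higher of the measured signal and the dimmest signal well above background.

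The 21 gene lists were fixed before the data were examined, and 532 of their 578 members were kept by the filter. The lists overlap, so their tests are not independent. The retinoic acid-induced list shares PDCD4, BTG2, ICAM1, IL1B and PLAT with the miR-21 list, and RARB and NRIP1 with the receptors and cofactors. With retinoid metabolism it shares CYP26A1, CYP26B1, DHRS3 and STRA6, among others. Lists were tested by camera with a preset inter-gene correlation of 0.01, again with an estimated correlation, and by fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes. List p-values were adjusted over the 21 lists of a comparison. Counts adjusted over the list alone use its members as the only genes tested.

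The comparisons, tests, lists, the first set of alternatives and the rule for naming genes were also set before the data were examined. The rule names, for each comparison of retinoic acid with vehicle, the 8 highest and 8 lowest called genes with the same sign on both arrays and signal well above background in the brighter channel on both, leaving out features without a gene symbol and placeholder symbols. It adds up to 4 called members of each list and a panel of 21 genes in every comparison: CYP26A1, DHRS3, RARB, RARA, RARG, CRABP2, FABP5, RBP1, TGM2, HOXA5, NRIP1, RARRES1, PLAAT4 (also RARRES3), IL1B, ICAM1, PLAT, PDCD4, VMP1, ESR1, TFF1 and CCND1. For differences it names 6 in each direction, and for vehicle levels 8. Where under 3 genes passed in a direction, the 5 with the smallest p are named and said not to pass. The text leaves out some list and panel members.

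Alternatives were the signal (no background correction, the software's processed signals and log10 ratio, the authors' table), the scaling (median centring, scale or quantile normalization), no filter or a stricter filter on dim probes, the mean of a gene's probes, an intensity trend with a robust prior, array weights, a replicate block, slide as a block, a minimum of 2-fold, fits to the compared arrays alone, a separate-channel fit, and leaving out each array. Added after the data had been examined were keeping outlier-marked spots, testing only genes measured on both arrays, slide as a random block, slide effects summing to 0, and the list tests under other signals, scalings and slide blocks. Control and spike-in spots were left out of all comparisons.

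The procedure was tested on simulated data after the real analysis had been run, with independent noise of the fitted size and no dye or slide effect. Among 100 genes changed by 1 log2 unit, it recovered 60 in the MCF7 6 h comparison, 59 in MCF7 48 h, 60 in MDA-MB-231 6 h and 46 in MDA-MB-231 48 h, and by 2 log2 units 99, 94, 99 and 94. For differences between lines it recovered 13.9% and 13.7% at 1 log2 unit at 6 and 48 h, and 88.4% and 86.0% at 2 log2 units. The share of false calls was 2.05% to 6.61% over the 9 comparisons. With no change simulated, a run made for the 8 comparisons other than vehicle levels, there were 0 calls. Of 4 lists shifted by 0.5, 4 were recovered, and 2 other lists were called. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.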

Results

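Gene expression was measured in 2 human breast carcinoma cell lines given all-trans retinoic acid, the vitamin A derivative that binds the retinoic acid receptors. MCF7 cells are estrogen receptor-positive and epithelial, and MDA-MB-231 cells are estrogen receptor-negative and mesenchymal. Growing cultures in medium with 5% charcoal-stripped serum and 10 nM estradiol received 1 µM retinoic acid or vehicle for 6 or 48 h. Each of the 8 arrays carried RNA from a retinoic acid culture in 1 dye and RNA from the vehicle culture of the same line and time in the other. The 4 combinations of line and time had 2 biological replicates each. Retinoic acid RNA was labelled with the green dye Cy3 in replicate 1 and with the red dye Cy5 in replicate 2. The number of arrays limits the precision of every value below.

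Median spot signals lay between 293 and 482 intensity units in red and between 200 and 291 in green, over local backgrounds of 61 to 65.5 and 68 to 74. The share of spots well above background was 65.7% to 79.0% in red and 61.2% to 72.8% in green. On MCF7 6 h replicate 2, 37.5% of the spots had been marked as outliers by the scanner software, against 0.261% to 0.904% on the other arrays. Those spots were removed, which left 12670 of the 23622 genes tested at MCF7 6 h with a value on both arrays. The log2 ratios of the dye-swapped arrays correlated weakly or negatively across genes, which are not independent replicates, with r = 0.10 at MCF7 6 h, 0.05 at MCF7 48 h, -0.32 at MDA-MB-231 6 h and 0.24 at MDA-MB-231 48 h. At MDA-MB-231 6 h, the part of the ratios that differed in sign between the dye orientations thus exceeded the part that both arrays shared.

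The levels in vehicle-treated cells gave the background against which retinoic acid acted in each line. MCF7 cells held more RNA of luminal and estrogen-responsive genes, and MDA-MB-231 cells more of mesenchymal and matrix protease genes. The estrogen-induced secreted factor TFF1 stood 10.36 ± 0.24 log2 units (SE, n = 3 MCF7 and 4 MDA-MB-231 arrays) higher in MCF7, the epithelial adhesion gene CDH1 9.18 ± 0.12 and the estrogen receptor gene ESR1 7.33 ± 0.13. For these genes MCF7 6 h replicate 2 had no value, nor did it for FOXA1. That luminal transcription factor stood 8.66 ± 0.16 log2 units higher in MCF7, with an MDA-MB-231 signal at background. The sulfatase SULF2 was higher in MCF7 too, with no size given since its signal was well above background on 1 of 4 MDA-MB-231 arrays. In the other direction, LDHB was at least 848-fold and the cytoskeletal linker MSN at least 790-fold higher in MDA-MB-231. The intermediate filament gene VIM differed by -9.29 ± 0.39 (n = 4 and 2), the glutathione peroxidase gene GPX1 by -8.77 ± 0.11 and the receptor kinase gene AXL by -8.38 ± 0.23, and GPX1, AXL, LDHB and MSN were measured on 4 arrays per line.

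Of 31 estrogen-responsive genes, 26 were higher and 2 lower in MCF7 (adjusted p = 4.96e-26), and of 25 luminal markers, 23 were higher and 1 lower (5.75e-38). Of 30 basal and mesenchymal markers, 23 were higher in MDA-MB-231 and 1 in MCF7 (1.13e-25). MDA-MB-231 also held more RNA for 18 of 25 genes of the plasminogen system and matrix proteases (6.80e-09), among them PLAU at -7.98 ± 0.21, and for 16 of 29 Wnt pathway genes (0.0200). Of 36 interferon-stimulated genes, 29 were higher in MDA-MB-231 (5.95e-09), but this list did not pass with an estimated correlation (adjusted p = 0.0845). Nor did NF-kB and inflammatory genes (18 of 27 higher in MDA-MB-231, adjusted p = 0.00164, and 0.114 with an estimated correlation), fatty acid oxidation and PPAR targets (14 of 23, 0.0425 and 0.422) or reported miR-21 targets (14 of 26, 0.0321 and 0.489). The other 12 lists did not pass. Luminal markers and Wnt genes no longer passed by camera with slide as a block (adjusted p = 0.0591 and 0.111). With the other signals and scalings their adjusted p by camera was 1.41e-39 to 6.61e-35 and 0.00788 to 0.0292. The slide block could not test genes without a value on MCF7 6 h replicate 2, among them the luminal markers CDH1, ESR1 and FOXA1.

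Of 23 genes of retinoid metabolism and transport 5 were higher and 7 lower in MCF7, and of 20 receptors and cofactors 6 and 5, and neither list passed (adjusted p = 0.990 and 0.803). The binding proteins CRABP1 and CRABP2 were higher in MCF7, by 6.13 ± 0.25 and 6.10 ± 0.12, as were the receptors RARA (2.41 ± 0.21) and RARG (1.70 ± 0.13). The fatty acid-binding protein FABP5 (-2.61 ± 0.13), the degrading enzyme CYP26B1 (-4.85 ± 0.27) and the synthesizing enzyme ALDH1A3 (-5.54 ± 0.13) were lower in MCF7. RARB was lower there too, with signal well above background on 1 of 4 MCF7 arrays. In all, 13056 of 23692 genes differed between vehicle-treated lines at an adjusted p under 0.05, 6561 higher and 6495 lower in MCF7, of which 6959 differed at least 2-fold. With slide as a block 5356 genes passed, 1322 higher and 4034 lower (median of all genes -0.33, against 0.05), and in the separate-channel fit 2494 were higher and 4233 lower. Under the slide block the line difference rested on slide 3, the 1 slide with both lines. It held MCF7 6 h replicate 2 and MDA-MB-231 48 h replicate 2, and genes missing on 1 of them could not be tested. The separate-channel fit used only genes measured on all arrays. Both counts thus come from fewer genes, and the first does not part slide from array. The stricter filter left 4113.

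After 6 h of retinoic acid, MCF7 cells held more RNA for the retinoic acid-degrading enzymes CYP26A1 and CYP26B1, and 13 of 33 genes widely described as retinoic acid-induced rose. On both arrays, the degrading enzyme CYP26B1 rose by 2.15 ± 0.31 log2 units (SE, n = 2), the peptidylarginine deiminase PADI3 by 2.12 ± 0.32, the apolipoprotein APOA1 by 1.99 ± 0.15, the transcription factor BATF by 1.94 ± 0.22 and the calcium-binding protein S100P by 1.90 ± 0.20. LYZL2 (1.95 ± 0.31), the aryl hydrocarbon receptor repressor AHRR (1.79 ± 0.23) and TNFAIP2 (1.79 ± 0.19) completed the 8 highest. On replicate 1 alone, the degrading enzyme CYP26A1 stood at 4.89 ± 0.20, the matrix protein gene TGFBI at 3.11 ± 0.20, the retinaldehyde reductase DHRS3 at 3.07 ± 0.48 and the antiproliferative gene BTG2 at 2.98 ± 0.19.

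Genes that fell on both arrays included GAS2L1 (-1.09 ± 0.15), FAM110B (-1.08 ± 0.11), DOK4 (-1.05 ± 0.15), TRIM36 (-1.04 ± 0.15) and the LIM-homeobox factor LHX2 (-1.02 ± 0.16). TMTC1 (-0.99 ± 0.12), RASL10A (-0.99 ± 0.14) and the tissue plasminogen activator gene PLAT (-0.95 ± 0.13) also fell. The lowest value was that of the translation elongation factor gene EEF1A1 (-2.01 ± 0.14). It is not read as a response, because its sign followed the dye in the other groups: with all spots kept, it stood at -1.78 and 1.60 on the MCF7 48 h arrays and at -1.19 and 1.91 on the MDA-MB-231 48 h arrays.

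By list, 13 of 33 genes widely described as retinoic acid-induced rose in MCF7 at 6 h and 1 fell (18 and 1 adjusted over the list alone; list adjusted p = 1.17e-49). They included CYP26A1, DHRS3, BTG2 and the receptor kinase RET (2.59 ± 0.20, 1 array). Of 23 genes of retinoid metabolism and transport 4 rose (5 adjusted over the list alone; 8.74e-10), with the retinol carrier STRA6 at 1.43 ± 0.21. Of 29 HOX genes 2 rose (7 adjusted over the list alone; 6.96e-05), HOXA5 by 1.75 ± 0.28 and HOXA4 by 1.16 ± 0.19. Of 30 TGF-beta and BMP pathway genes 4 rose, all on 1 array (5 adjusted over the list alone; 0.00315). These were TGFBI, the BMP target ID1 (2.55 ± 0.26), the pseudoreceptor BAMBI (2.14 ± 0.24) and SMAD3 (1.32 ± 0.18). On replicate 2, with outlier-marked spots kept, they stood at 0.60, 0.37, 0.06 and 0.38.

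Among 26 reported miR-21 targets 4 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.0355), with BTG2, MARCKS (1.47 ± 0.19), TIMP3 (1.33 ± 0.17) and PDCD4 (1.16 ± 0.17) measured on 1 array and PLAT lower. With outlier-marked spots kept, replicate 2 stood at 0.44 for BTG2, -0.37 for MARCKS, 0.51 for TIMP3 and 0.11 for PDCD4. BTG2 was the 1 of 22 growth arrest genes that rose (6 and 1 fell adjusted over the list alone; 0.0225). The medians of the TGF-beta, growth arrest and miR-21 lists were slightly below 0 (-0.04, -0.01 and -0.01), while their means (0.21, 0.25 and 0.18) and tests were positive. DNA replication and G1/S genes tested as lower with 0 of 30 passing (mean -0.20, 0.00315), but not with an estimated correlation (adjusted p = 0.159); the other 6 calls held with it. The growth arrest and miR-21 lists turned lower on genes measured on both arrays (adjusted p = 0.565 and 0.203), and TGF-beta genes with outlier-marked spots kept (0.998); over all alternatives these ranged from 0.0115 to 0.783, 0.0171 to 0.970 and 0.00117 to 0.998. Of the retinoic acid-induced list, the nuclear receptor corepressor NRIP1 (1.45 ± 0.19) and the epithelial transcription factor ELF3 (2.57 ± 0.25) also rose. Outside the lists that passed, CASP9 (1.45 ± 0.21), the endothelial marker CDH5 (1.30 ± 0.18) and NQO1 (1.14 ± 0.18) rose and the progesterone receptor gene PGR (-1.06 ± 0.17) and FZD4 (-1.23 ± 0.17) fell, all 7 genes on 1 array. With outlier-marked spots kept, replicate 2 stood at -0.02 for NRIP1, 1.03 for ELF3, 0.02 for CASP9 and 0.62 for CDH5. There NQO1 stood at 0.12, PGR at 0.29 and FZD4 at -0.81. The monocyte marker CD14 rose (1.23 ± 0.18) and the potassium channel KCNK5 fell (-0.77 ± 0.12) on both. RARA (0.00 ± 0.20), RARB (0.02 ± 0.20), CRABP2 (0.35 ± 0.25), ESR1 (0.62 ± 0.19) and CCND1 (-0.30 ± 0.25) did not pass.

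In total, 188 of 23622 genes passed in MCF7 at 6 h, 151 higher and 37 lower, and 104 of them were measured on replicate 1 or replicate 2 alone. The count rested on replicate 1: without it 0 genes passed, and without replicate 2 there were 283. Keeping the outlier-marked spots also left 0 (2223 at an unadjusted p under 0.05) and put CYP26A1 on replicate 2 at 0.52, and a fit to these 2 arrays alone left 0 (1310 unadjusted). A block for slide left 220 or 17, depending on whether slide 1 or the mean of the slides was the reference.

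At 48 h, MCF7 cells still held more RNA for CYP26A1 and DHRS3, together with the hypoxia-inducible factor EPAS1 and the serine protease TMPRSS4, and less for ABCA12, CLCA2, COL4A6 and BMP7. CYP26A1 rose by 3.35 ± 0.14 (n = 2), DHRS3 by 3.23 ± 0.34, the acyltransferase MBOAT1 by 2.87 ± 0.36, EPAS1 by 2.47 ± 0.17, TMPRSS4 by 2.42 ± 0.15 and ELF3 by 2.36 ± 0.18. The carboxypeptidase inhibitor LXN (1.94 ± 0.19) and the imprinted noncoding RNA H19 (1.87 ± 0.14) followed. The lipid transporter ABCA12 fell by 1.67 on the log2 scale, CLCA2 by 1.64, the collagen gene COL4A6 by 1.59 and the growth factor gene BMP7 by 1.56, with SE of 0.14, 0.22, 0.15 and 0.15. HGD (-1.46 ± 0.14), CDH18 (-1.36 ± 0.17), STOM (-1.28 ± 0.13) and CLSTN2 (-1.26 ± 0.13) fell too.

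Of 33 genes widely described as retinoic acid-induced 6 rose (14, with 1 fallen, adjusted over the list alone; adjusted p = 3.80e-36), and of 23 retinoid metabolism genes 2 rose (3 and 1 fell adjusted over the list alone; 1.43e-09). BAMBI (1.58 ± 0.17), BTG2 (1.29 ± 0.14), TIMP3 (1.24 ± 0.12) and, on 1 array, TGFBI (2.23 ± 0.20) rose, and the annexin ANXA1 (-1.18 ± 0.13) and the Wnt receptor FZD4 (-1.11 ± 0.12) fell. Small shifts without a passing member made up the other calls, upward in HOX genes (mean 0.15, 0.00877), estrogen-responsive genes (0.15, 0.00988), DNA replication and G1/S genes (0.17, 8.93e-05) and sterol and fatty acid synthesis genes (0.20, 7.02e-05). All 6 calls held with an estimated correlation. With slide effects summing to 0, retinoic acid-induced and sterol synthesis genes turned lower (adjusted p = 0.367 and 0.573; over all alternatives 1.31e-42 to 0.525 and 8.61e-07 to 0.903). TFF1 had opposite signs on the arrays (-1.62 and 0.95), and ESR1 (0.15 ± 0.13), NRIP1 (0.68 ± 0.13), PDCD4 (0.47 ± 0.12) and HOXA5 (0.32 ± 0.28) did not pass.

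In MCF7 at 48 h, 59 of 23658 genes passed, 34 higher and 25 lower. With slide as a block the count was 65 with slide 1 as the reference and 0 (413 at an unadjusted p under 0.05) with slide effects summing to 0, and a fit to these 2 arrays alone gave 0 (1366 unadjusted). Without replicate 1 or replicate 2 it was 0 (1030 and 1248 unadjusted), and median centring left 1. Of the genes that had risen at 6 h, 28 were also higher at 48 h, against 0.218 expected if the calls were independent, and 5 were lower at both times. The calls were not independent, since both times shared 1 estimate of each gene's spread.

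Testing 48 h against 6 h directly, the retinoic acid effect in MCF7 differed for 2 of 23586 genes. These were the cyclooxygenase gene PTGS1 (-3.80 ± 0.24) and the sphingomyelinase gene SMPD3 (-3.43 ± 0.24), both measured on 1 of the 6 h arrays and named after their values were seen. No gene measured on all arrays passed, and 989 genes had an unadjusted p under 0.05. The uncalled lower genes with the smallest p were CLCA2 (-1.65 ± 0.31, adjusted p = 0.420), S100P (-1.44 ± 0.29, 0.480), CEMIP (-1.37 ± 0.21, 0.379), COL4A6 (-1.16 ± 0.21, 0.379) and PGM2L1 (-1.02 ± 0.20, 0.480), and CYP26A1 stood at -1.54 ± 0.25 (0.379). PLAC1 (1.15 ± 0.19), TPPP3 (1.07 ± 0.17), KCNK5 (1.04 ± 0.16), SMTNL2 (0.90 ± 0.17) and CCDC88B (0.83 ± 0.16) had the smallest p among the uncalled higher ones, at adjusted p of 0.379 or 0.420. As lists, retinoic acid-induced genes had lower ratios at 48 h than at 6 h (mean -0.47, adjusted p = 1.54e-12) and DNA replication genes higher ones (0.37, 7.47e-10). TGF-beta genes (-0.18, 0.0499) and retinoid metabolism genes (-0.23, 0.0499) also passed downward, the latter not with an estimated correlation (adjusted p = 0.0911). These list tests were not repeated with outlier-marked spots kept or on genes measured on both arrays. Within slide 1, which held 3 of these 4 arrays, 7 genes differed, 2 of them shared with the fit to all arrays. Both calls ended (0 genes, and 53 to 1017 at an unadjusted p under 0.05 by limma) with the processed signals, the log10 ratio, the authors' table, median centring, scale normalization, the mean of probes, array weights or outlier-marked spots kept, among others.

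In MDA-MB-231 cells, 6 h of retinoic acid raised a small group of genes, 7 of them with a gene symbol. DHRS3 rose by 3.62 ± 0.34 (n = 2), the receptor RARB by 2.45 ± 0.20, the semaphorin and VEGF coreceptor NRP2 by 2.02 ± 0.13, NRIP1 by 1.83 ± 0.13, the lipoprotein lipase inhibitor ANGPTL4 by 1.75 ± 0.12, the cytokine IL1B by 1.49 ± 0.13 and the signalling adaptor SH2D1B by 1.24 ± 0.12. No gene fell at an adjusted p under 0.05. The 5 lower genes with the smallest p did not pass: the matrix protein THBS1 stood at -1.17 ± 0.16 (adjusted p = 0.151), TOX at -0.73 ± 0.12 (0.244), KLF6 at -0.71 ± 0.14 (0.499), ARID5B at -0.68 ± 0.12 (0.343) and OXTR at -0.68 ± 0.12 (0.301). CYP26A1, whose vehicle signal lay at background, stood at 0.55 ± 0.14 and did not pass, nor did PLAT (0.81 ± 0.13, adjusted p = 0.191).

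Of 33 genes widely described as retinoic acid-induced 4 rose (10 adjusted over the list alone; list adjusted p = 2.68e-56), of 20 receptors and cofactors RARB and NRIP1 rose (9.94e-11), and of 23 retinoid metabolism genes DHRS3 rose (3.59e-05). IL1B was the 1 riser of 26 miR-21 targets (3.10e-07), and ANGPTL4 of 23 fatty acid oxidation and PPAR targets (0.000649). RARB, NRIP1, DHRS3 and IL1B are also in the retinoic acid-induced list, so the receptor, retinoid metabolism and miR-21 calls are not separate from it. Without a passing member, growth arrest genes (mean -0.12, 0.000187), Wnt pathway genes (-0.07, 0.00506) and stress genes of the endoplasmic reticulum (-0.07, 0.0448) tested as lower. Interferon-stimulated genes (0.13, 3.59e-05), NF-kB genes (0.12, 0.000187) and mitosis genes (-0.08, 0.00247) passed too, but not with an estimated correlation (adjusted p = 0.105, 0.0726 and 0.146). The other 8 of the 11 calls held with it. NF-kB genes turned lower with slide as a block in either form (adjusted p = 0.427 and 0.663; over all alternatives 1.32e-07 to 0.663).

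At 6 h, 11 of 23714 genes passed in MDA-MB-231, all higher and all on both arrays, and 384 had an unadjusted p under 0.05. The count fell to 0 with slide as a block in either form (565 and 416 unadjusted), to 0 without replicate 1 and to 1 without replicate 2. With median centring in place of loess it was also 0 (59 unadjusted).

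At 48 h, the 11 genes raised in MDA-MB-231 at 6 h, among them DHRS3, RARB and IL1B, were raised as well, together with CST1, CST2, CYP26A1 and CFI, while OLFML2A, S100A4 and the Wnt receptor FZD8 fell. The cystatins CST1 and CST2 rose by 3.03 ± 0.19 and 2.94 ± 0.21 (n = 2), and the sequences of these paralogs are nearly identical. ANGPTL4 rose by 2.90 ± 0.12, IL1B by 2.74 ± 0.13, RARRES1 by 2.39 ± 0.13, DHRS3 by 2.38 ± 0.34, CYP26A1 by 2.37 ± 0.14 and the complement factor CFI by 2.36 ± 0.14. The transglutaminase TGM2 (2.00 ± 0.16), RARB (1.73 ± 0.20) and NRIP1 (1.54 ± 0.13) also rose. The secreted protein gene OLFML2A fell by 1.95, SLITRK6 by 1.60, the calcium-binding mesenchymal gene S100A4 by 1.53 and GAS2L1P2 by 1.51, with SE of 0.13, 0.19, 0.17 and 0.22. PDE8B (-1.47 ± 0.16), ANKRD1 (-1.46 ± 0.12), RASL10A (-1.43 ± 0.14) and the Wnt receptor FZD8 (-1.43 ± 0.18) also fell.

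Of 33 genes widely described as retinoic acid-induced 10 rose (18 adjusted over the list alone; list adjusted p = 3.76e-67). Among 27 NF-kB and inflammatory genes 4 rose (12 adjusted over the list alone; 2.11e-32): IL1B, the prostaglandin synthase PTGS2 (1.61 ± 0.16), the adhesion molecule ICAM1 (1.29 ± 0.13) and IL1A (1.27 ± 0.14). Of 36 interferon-stimulated genes GBP1 rose (0.92 ± 0.15; 7 adjusted over the list alone; 1.15e-09), and of 29 apoptosis genes CASP1, which processes IL1B, rose (0.91 ± 0.13; 3 adjusted over the list alone; 3.34e-05). Of 23 fatty acid oxidation and PPAR targets ANGPTL4 and ACSL5 (0.79 ± 0.12) rose (5 adjusted over the list alone; 2.63e-09). Retinoid metabolism genes (2 of 23 rose, 0.00114), receptors and cofactors (2 of 20, 0.00747) and miR-21 targets (2 of 26, IL1B and ICAM1, 5.29e-07) also passed. Both miR-21 targets that rose are also in the retinoic acid-induced list.

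Among the lists that tested as lower, 2 of 29 Wnt pathway genes fell, FZD8 and DKK3 (-0.83 ± 0.13; 4 adjusted over the list alone; adjusted p = 1.87e-05). Of 30 basal and mesenchymal markers S100A4 and VIM fell (5 fell and 2 rose adjusted over the list alone; 0.000489), but VIM rested on replicate 1 (-1.58 ± 0.21) and stood at 0.71 on replicate 2 when outlier-marked spots were kept. Of 30 TGF-beta genes INHBB fell (-1.37 ± 0.13; 1 rose and 1 fell adjusted over the list alone; 0.0269). All 11 calls held with an estimated correlation. ELF3 of the retinoic acid-induced list rose by 2.08 ± 0.18. Outside the lists that passed, the cholesterol exporter ABCA1 (1.52 ± 0.21) rose, and the cell cycle inhibitor gene CDKN1C (-1.33 ± 0.22) and the LDL receptor regulator MYLIP (-0.95 ± 0.12) fell. RARA (-0.25 ± 0.14), FABP5 (-0.26 ± 0.14), CCND1 (-0.08 ± 0.18), PLAT (0.63 ± 0.13) and PLAAT4 (0.98 ± 0.18, adjusted p = 0.102) did not pass.

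In all, 152 of 23690 genes passed in MDA-MB-231 at 48 h, 98 higher and 54 lower, and the 11 genes that had risen at 6 h were all among the 98. With slide as a block the count was 0 with slide 1 as the reference (805 at an unadjusted p under 0.05) and 63 with slide effects summing to 0. It was 26 without replicate 1 and 40 without replicate 2, and median centring left 3, all higher.

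Between 48 and 6 h, the retinoic acid effect in MDA-MB-231 differed for 7 of 23682 genes. It was larger at 48 h for CST1 (2.49 ± 0.26), CFI (2.25 ± 0.20), the serine protease inhibitors SERPINB4 (2.25 ± 0.17) and SERPINB3 (2.13 ± 0.20), which are close paralogs, RARRES1 (1.96 ± 0.18) and BPI (1.87 ± 0.17). It was lower for OLFML2A (-1.89 ± 0.18). At 6 h SERPINB4, SERPINB3 and BPI had no signal well above background. CYP26A1 (1.82 ± 0.20, adjusted p = 0.0913, with a vehicle signal near background at both times), TGM2 (1.55 ± 0.23, 0.147) and IL1B (1.25 ± 0.19, 0.147) did not pass, nor did S100A4 (-1.62 ± 0.24, 0.147), P2RY6 (-1.39 ± 0.21, 0.195), INHBB (-1.32 ± 0.19, 0.160), ANKRD1 (-1.05 ± 0.18, 0.216) or FBLN1 (-0.98 ± 0.16, 0.195). As lists, retinoic acid-induced genes (mean 0.33, adjusted p = 6.85e-15), NF-kB genes (0.43, 1.18e-20) and PPAR targets (0.17, 0.000368) had higher ratios at 48 h than at 6 h, and Wnt pathway (-0.18, 0.0190) and basal and mesenchymal genes (-0.17, 0.0190) lower ones. Interferon-stimulated and apoptosis genes passed upward (0.000796 and 0.00255), but not with an estimated correlation (adjusted p = 0.258 and 0.162). Within slide 2, which held 3 of these 4 arrays, 1 gene passed and it was not among the 7, and with slide as a block 0 passed (480 at an unadjusted p under 0.05). None passed with the processed signals, the log10 ratio, the authors' table, median centring or scale normalization. The stricter filter, the intensity trend and a fit to the compared arrays alone left none either. The count stayed at 7 with outlier-marked spots kept.

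**Figure D1:**
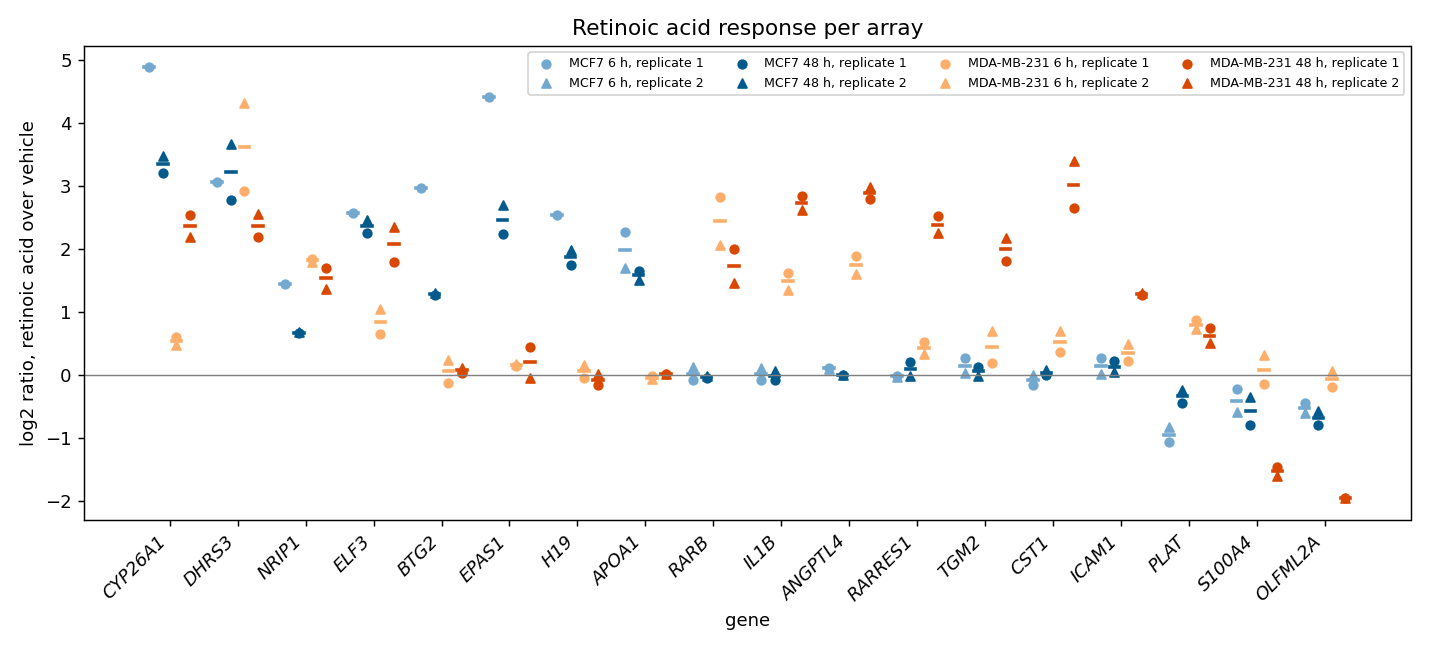
Log2 ratio of retinoic acid over vehicle (vertical axis) for 18 genes in the 4 groups of line and time, with circles for replicate 1, triangles for replicate 2 and bars at the mean of the arrays measured. The genes all fall under the rule for named genes but were picked for the plot after their values were seen. CYP26A1 lies at 4.89 in MCF7 at 6 h on 1 array and at 3.35 at 48 h. In MDA-MB-231 it lies at 0.55 (vehicle signal at background) and 2.37. IL1B lies at 1.49 and 2.74 in MDA-MB-231, while its signal was not well above background in MCF7.

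The title of the series asks how retinoids act in estrogen receptor-positive and -negative cells, and the difference between the lines was tested at each time. At 6 h, the log2 ratio was higher in MCF7 for CYP26A1 (4.34 ± 0.25, MCF7 minus MDA-MB-231, with 1 MCF7 array and a vehicle signal at background in MDA-MB-231), APOA1 (2.03 ± 0.21) and the glycoprotein MAG (1.51 ± 0.19). With outlier-marked spots kept, which adds MCF7 replicate 2, the CYP26A1 difference was 2.16 and did not pass. In MDA-MB-231, APOA1 and MAG were well above background on 1 of the 6 h arrays. The ratio was higher in MDA-MB-231 for RARB (-2.42 ± 0.28), NRP2 (-2.00 ± 0.18), PLAT (-1.75 ± 0.19), ANGPTL4 (-1.64 ± 0.18) and IL1B (-1.47 ± 0.19). In MCF7 at 6 h, NRP2 and IL1B were well above background on neither array and RARB and ANGPTL4 on 1. S100P (1.67 ± 0.29, adjusted p = 0.146), TNFAIP2 (1.59 ± 0.27, 0.131), FST (1.47 ± 0.23, 0.107), KRT15 (1.28 ± 0.24, 0.190) and LCN2 (0.99 ± 0.19, 0.191) did not pass, nor did HOXA5 (1.70 ± 0.39, 0.276).

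In total 28 of 23613 genes differed at 6 h, 21 with a higher and 7 with a lower ratio in MCF7, and 9 of them were measured on all 4 arrays. As lists, retinoic acid-induced (mean difference 0.52, adjusted p = 2.28e-11), retinoid metabolism (0.36, 8.81e-05), HOX (0.29, 0.000417), growth arrest (0.38, 5.16e-05) and TGF-beta genes (0.26, 0.000106) had higher ratios in MCF7. DNA replication genes had lower ones (-0.24, 0.000417), though not with an estimated correlation (adjusted p = 0.0854). With slide as a block 0 genes passed (361 at an unadjusted p under 0.05) and none of the 6 list calls held, the retinoic acid-induced and DNA replication lists turning sign (adjusted p = 0.646 and 0.951). The lines were never on the same slide at the same time, so slide and line can be parted only through that model. Its slide effects come from dye-swapped pairs, 1 of them with MCF7 6 h replicate 2 and its many outlier-marked spots. The model thus does not part slide from dye orientation or array, and it cannot test genes without a value on that array.

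At 48 h, the log2 ratio was higher in MDA-MB-231 for CST1 (-2.99 ± 0.26), ANGPTL4 (-2.89 ± 0.18), CST2 (-2.86 ± 0.30), IL1B (-2.74 ± 0.19), the prostaglandin transporter SLCO2A1 (-2.48 ± 0.23), CFI (-2.40 ± 0.20), RARRES1 (-2.29 ± 0.18) and TGM2 (-1.94 ± 0.23). Of these, ANGPTL4 and SLCO2A1 had signal well above background on both MCF7 48 h arrays and the others did not. MCF7 cells had higher ratios for TMPRSS4 (2.51 ± 0.21), EPAS1 (2.26 ± 0.24), H19 (1.94 ± 0.19), APOA1 (1.57 ± 0.21), ANKRD1 (1.51 ± 0.18) and TPPP3 (1.29 ± 0.17). In MDA-MB-231 at 48 h, TMPRSS4 was well above background on neither array and H19 and APOA1 on 1, while ANKRD1 was so on neither MCF7 array and had fallen in MDA-MB-231. RARB (-1.77 ± 0.28, adjusted p = 0.0762), ICAM1 (-1.15 ± 0.19, 0.0762), CYP26A1 (0.98 ± 0.20, 0.195) and DHRS3 (0.85 ± 0.48, 0.918) did not pass.

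At 48 h the difference passed for 45 of 23627 genes, 38 of them with the higher ratio in MDA-MB-231. It passed for 0 without MCF7 48 h replicate 1 or 2 (1960 and 899 at an unadjusted p under 0.05), for 6 and 11 without MDA-MB-231 48 h replicates 1 and 2, and for 0 with median centring (173 unadjusted). NF-kB genes (mean difference -0.50, adjusted p = 3.04e-17), interferon-stimulated genes (-0.37, 4.16e-09), retinoic acid-induced genes (-0.29, 5.36e-07), PPAR targets (-0.23, 0.000114), miR-21 targets (-0.18, 0.00196) and plasminogen and protease genes (-0.15, 0.0260) had lower ratios in MCF7. Estrogen-responsive (0.21, 0.0107), growth arrest (0.21, 0.0107), HOX (0.21, 0.0171), Wnt (0.19, 0.0207), sterol synthesis (0.19, 0.0107), TGF-beta (0.17, 0.0230) and stress genes (0.17, 0.0242) had higher ones. DNA replication (0.18, 0.0107) and apoptosis genes (-0.16, 0.0107) passed, but not with an estimated correlation (adjusted p = 0.160 and 0.136). With slide as a block 0 genes passed (553 at an unadjusted p under 0.05), 9 of the 15 list calls held, and the sterol, protease and stress lists turned sign (adjusted p = 0.00391, 0.706 and 0.919).

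**Figure D2:**
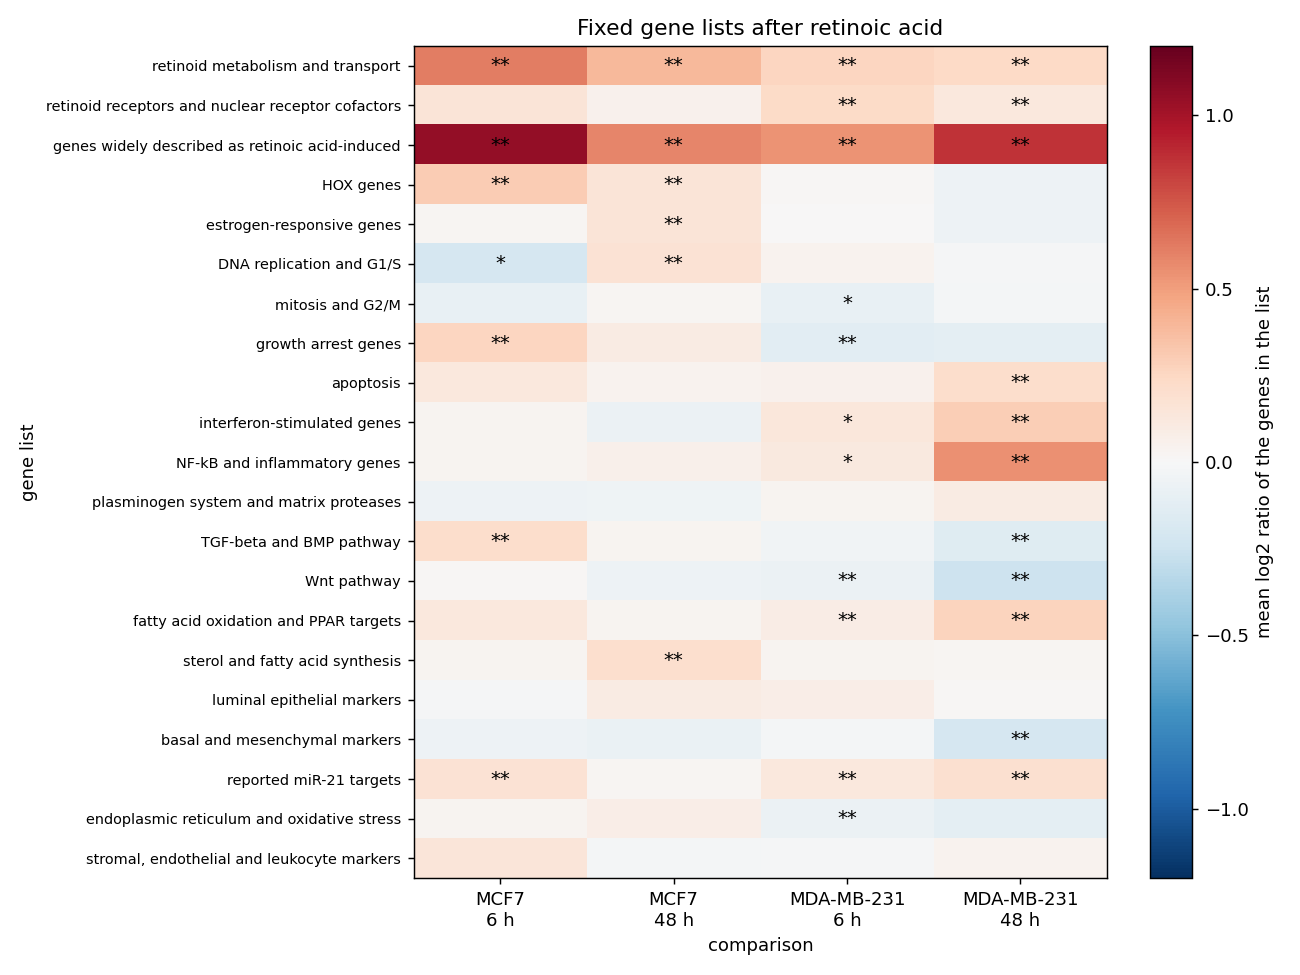
Mean log2 ratio of retinoic acid over vehicle (colour, from -1.2 in blue to 1.2 in red) for the 21 gene lists (rows) in the 4 groups of line and time (columns); 1 star marks an adjusted p under 0.05 with the preset correlation and 2 stars also with an estimated correlation. The retinoic acid-induced list stands highest in each column, at means of 1.06, 0.58, 0.54 and 0.87 in MCF7 at 6 and 48 h and MDA-MB-231 at 6 and 48 h, and no starred list changed sign under the 6 other signals and scalings.

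Across the groups, DHRS3 was the gene called higher at both times in both lines. MCF7 at 6 h and MDA-MB-231 at 48 h shared 10 genes called higher, among them CYP26A1, ELF3, NRIP1 and GDF15, against 0.627 expected if the calls were independent (Fisher's exact test, one-sided, p = 7.40e-10). Of the lower calls, these groups shared GAS2L1 and RASL10A, named after their values were seen (0.0847 expected, Fisher's exact test, one-sided, p = 0.00325). All groups shared 1 estimate of each gene's spread, so calls were not independent, and these expected counts and p-values take no account of that. In MCF7 at 6 h, DHRS3, CYP26A1, ELF3 and NRIP1 were measured on replicate 1 alone. Luminal markers (adjusted p from 0.0692 to 0.873), plasminogen and protease genes (0.0667 to 0.382) and stromal, endothelial and leukocyte markers (0.196 to 0.613) passed in none of the 4 comparisons of retinoic acid with vehicle.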

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

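The tests of other splits of the arrays and of dye bias were set before their results were seen, whereas those of signal compression, of a weaker second culture and of dim signal, as given here, were chosen afterwards, some in place of an earlier form that is named beside them.

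Genes whose response to retinoic acid differed between the lines are listed first, since each passed a test of the difference itself (log2, MCF7 minus MDA-MB-231). At 6 h these were CYP26A1 at 4.34 (1 MCF7 array, and a vehicle signal at background in MDA-MB-231), APOA1 at 2.03, MAG at 1.51, RARB at -2.42, NRP2 at -2.00, PLAT at -1.75, ANGPTL4 at -1.64 and IL1B at -1.47. At 48 h they were TMPRSS4 at 2.51, EPAS1 at 2.26, H19 at 1.94, APOA1 at 1.57, ANKRD1 at 1.51, TPPP3 at 1.29, CST1 at -2.99, ANGPTL4 at -2.89, CST2 at -2.86, IL1B at -2.74, SLCO2A1 at -2.48, CFI at -2.40, RARRES1 at -2.29 and TGM2 at -1.94.

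Genes whose response differed between 48 and 6 h passed a test of that difference in the same fit. In MDA-MB-231 the response of CST1 was higher at 48 h by 2.49, of SERPINB4 by 2.25, of CFI by 2.25, of SERPINB3 by 2.13, of RARRES1 by 1.96 and of BPI by 1.87, while OLFML2A stood at -1.89. In MCF7, PTGS1 stood at -3.80 and SMPD3 at -3.43, each measured on 1 of the 6 h arrays.

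Spots for added control transcripts, which no comparison used, gave signal on 2 arrays. In red, 166 of 320 spots were well above background on MCF7 6 h replicate 1 and 127 on MDA-MB-231 6 h replicate 1, against 4 to 40 on the other arrays. Their median red signals there were 87.9 and 88.1, against 69.3 and 71.6 for the negative control spots. No array stood apart from the other 3 of its line in the vehicle levels of the 50 groups of 4 tested by Dixon's rule, of which about 1 in 20 would by chance. Genes missing on an array of the line were not tested, among them ESR1, TFF1 and CRABP2 in MCF7, which had no value on 6 h replicate 2. The test thus says little of that array. Each group also mixed 6 and 48 h arrays, and differences between times widen its range.

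The large set of genes that differed between vehicle-treated lines was set against other splits of the 8 arrays. Of the 35 splits into 4 and 4, 1 gave as many genes, the real one with 13056, and the highest of the others gave 2. Every other split puts both lines on each side, so the line difference enters its spread and keeps its count low. The test thus cannot decide on chance, nor does it part line from slide.

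In MCF7 at 6 h, many calls rested on replicate 1 alone and the retinoic acid ratios of replicate 2 were smaller. Dye bias of replicate 1 is argued against, because 93.1% of 101 such calls had the same sign on MCF7 48 h replicate 2, whose dyes run the other way (median 0.69), where 51.95% of all genes kept theirs. Signal compression in the red channel of replicate 2 was tested over 6028 genes with unmarked spots and retinoic acid signal well above background on all arrays. For these genes it is argued against as well: the slope of the line difference in that channel was 0.929, within the 0.854 to 1.02 of the other MCF7 arrays. In the vehicle channel, the form of the test set first, the slope was 0.888. The outlier-marked spots of replicate 2 were not in the test, so it cannot decide on compression there. A weaker response of the second culture stays open: its ratios had a slope of 0.600 ± 0.066 on those of replicate 1 over 19 genes called in MCF7 at 48 h, below 0.929, while the same slope between the 48 h arrays was 1.07. This met the condition first set for a weaker culture, but the condition was changed after the value was seen, because 37.5% of the spots of that array were outlier-marked, and a weaker culture and damage to the array cannot be told apart.

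In MDA-MB-231, 35 genes were raised at 48 h and had a higher ratio there than in MCF7, among them IL1B, ANGPTL4, CST1, CFI and TGM2. Signal too dim in MCF7 to show a rise is argued against as a set for the 12 that were well above background on both MCF7 48 h arrays: with the rise of MDA-MB-231 applied to their MCF7 signal above the 95th percentile of undetected genes, the expected ratio was over 2 SE above the measured one for 91.7% (11 genes, not AK026140; medians 1.27 expected and -0.32 measured), and for 12 and 11 genes with the median or the 99th percentile as background. This replaced the share with a ratio in MCF7 under 0.5 times that in MDA-MB-231 (100%), which the choice of the genes fixes. For the other 23, dim signal and an absent response cannot be told apart, as the median ratio was -0.01 in MCF7 and 2.00 in MDA-MB-231, and an earlier test, which added the MDA-MB-231 rise to the MCF7 signal and would have shown 100% of them, was set aside because that signal is mostly background and offset. For the 11 genes a weaker response of MCF7 cells may be the source, as a hypothesis, but line and slide were parted only by a slide block. Under that block, which does not part slide from dye orientation, 0 genes differed between the lines at 48 h by limma (553 at an unadjusted p under 0.05).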

How the results depend on the processing

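Counts of called genes depended heavily on the processing, while the list tests and, where still measured, the signs of the named genes depended less on it. Keeping outlier-marked spots, testing only genes measured on both arrays, slide as a random block, slide effects summing to 0, the list tests under other signals, scalings and slide blocks, and the named genes under the processed signals, the authors' table, scale normalization and outlier-marked spots were chosen after seeing the data. Where a value below moved, the cause was not tested, except where fewer arrays or genes were used. Counts are in the order MCF7 6 h, MCF7 48 h, MDA-MB-231 6 h, MDA-MB-231 48 h, line at 6 h, line at 48 h, time in MCF7 and time in MDA-MB-231, against 188, 59, 11, 152, 28, 45, 2 and 7 as reported. Over all settings with a count of 0 by limma, 53 to 2223 genes had an unadjusted p under 0.05.

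The signal and scaling moved most counts. The software's processed signals gave 0, 5, 0, 2, 0, 0, 0 and 0, its log10 ratio 5, 12, 5, 22, 0, 4, 0 and 0, and median centring 4, 1, 0, 3, 0, 0, 0 and 0. The authors' table gave 67, 24, 13, 93, 4, 25, 0 and 0, scale normalization 23, 88, 10, 114, 6, 39, 0 and 0, and no background correction 124, 53, 8, 150, 24, 49, 2 and 5. The share of higher calls rose under median centring in MCF7 at 6 h (4 of 4) and 48 h (1 of 1), under scale normalization in MCF7 at 6 h (22 of 23), and in MDA-MB-231 at 48 h under the processed signals (2 of 2), the log10 ratio (20 of 22) and median centring (3 of 3). Of the line differences, 4 of 4 were lower in MCF7 at 48 h under the log10 ratio and 4 of 6 at 6 h under scale normalization. In the vehicle comparison the processed signals moved the median of all genes from 0.05 to 0.24, and no scaling moved it by over 0.1 in the other comparisons.

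Among filters and models, the stricter filter, which tested 8594 genes, gave 60, 9, 1, 23, 1, 6, 0 and 0, and no filter 152, 59, 9, 157, 28, 51, 2 and 6. The mean of a gene's probes gave 186, 44, 12, 149, 20, 57, 0 and 6, the intensity trend with a robust prior 41, 9, 7, 84, 8, 20, 0 and 0, array weights (0.681 for MCF7 6 h replicate 2) 26, 104, 14, 164, 8, 67, 0 and 8, and a minimum of 2-fold 160, 55, 11, 113, 28, 45, 2 and 7. Fits to the compared arrays alone gave 0, 0, 8, 293, 5, 37, 0 and 0, keeping outlier-marked spots 0, 13, 8, 110, 1, 33, 0 and 7, and genes measured on both arrays 55, 60, 11, 159, 5, 54, 0 and 7.

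With slide as a block the counts were 220, 65, 0, 0, 0, 0, 5 and 0 with slide 1 as the reference, 17, 0, 0, 63, 0, 0, 5 and 0 with slide effects summing to 0, and 126, 39, 9, 135, 20, 32, 2 and 7 with slide as a random block (correlation 0.150). The fixed forms do not part slide from dye orientation, and their line differences leave out genes without a value on MCF7 6 h replicate 2.

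A replicate block, which is also a block for dye orientation, gave 108, 56, 12, 176, 11, 45, 0 and 5. The labels give same-numbered samples no common origin, and not every correlation of their deviations from the group means was above 0.1, so the numbers are not taken to pair the samples: r was 0.29, 0.35 and 0.70 among MCF7 6 h and the 2 MDA-MB-231 groups, and -0.19, -0.04 and -0.01 between MCF7 48 h and these.

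Leaving out 1 array gave 0 to 283 genes in MCF7 at 6 h, 0 to 102 in MCF7 at 48 h, 0 to 11 in MDA-MB-231 at 6 h and 26 to 141 at 48 h, 0 to 102 for lines at 6 h and 0 to 51 at 48 h, 0 to 7 for time in MCF7 and 0 to 1 in MDA-MB-231. The group left with 1 array is assumed to vary like the others, and its dye effect no longer cancels. In MCF7 at 6 h, 0 passed without its replicate 1, 283 without its replicate 2, 19 without either MCF7 48 h array, 54 without either MDA-MB-231 48 h array and 87 without either MDA-MB-231 6 h array. In MCF7 at 48 h, 0 passed without either of its arrays, 102 without either MCF7 6 h array and 24 without either MDA-MB-231 48 h array. In MDA-MB-231 at 6 h, 0 passed without its replicate 1, 1 without its replicate 2 and 3 without either MCF7 48 h array, and at 48 h 26 without its replicate 1, 40 without its replicate 2 and 76 without either MCF7 48 h array. For lines at 6 h, 0 passed without MCF7 6 h replicate 1, 102 without its replicate 2, 5 without either MCF7 48 h array, and 5 and 7 without MDA-MB-231 6 h replicates 1 and 2, and at 48 h 0 without either MCF7 48 h array and 6 and 11 without MDA-MB-231 48 h replicates 1 and 2. For time in MCF7, 7 passed without MCF7 6 h replicate 2, 2 without either MDA-MB-231 6 h array and 0 without any other, and in MDA-MB-231 1 passed without MDA-MB-231 48 h replicate 2 and 0 without any other.

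The vehicle comparison, at 13056 genes, gave 4113 with the stricter filter, 5356 with slide as a block, 6959 with a minimum of 2-fold and 6727 in the separate-channel fit, which tested 12584 genes and shared 6266 of its calls. It gave 11101 to 14590 without 1 array, 10793 without time as a covariate and 11442 to 16831 under the other settings.

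Of 84 list tests of retinoic acid against vehicle, 35 passed as reported, 22 with slide as a block, 21 with slide effects summing to 0 and 31 to 39 under the other settings except fry. By fry, run only on members measured on all arrays, 17 passed. The signals and scalings turned the sign of none of these calls. In MCF7 at 6 h, growth arrest genes turned lower by fry, on genes measured on both arrays and with slide effects summing to 0 (adjusted p = 0.473, 0.565 and 0.774). There, miR-21 targets did so by fry, with outlier-marked spots kept, on genes measured on both arrays and with slide effects summing to 0 (0.162, 0.671, 0.203 and 0.774), and TGF-beta genes with outlier-marked spots kept (0.998). With slide effects summing to 0, retinoic acid-induced and sterol synthesis genes turned lower in MCF7 at 48 h (0.367 and 0.573), and NF-kB genes turned lower in MDA-MB-231 at 6 h with slide as a block in either form (0.427 and 0.663).

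In the line differences a slide block turned the sign of retinoic acid-induced and DNA replication genes at 6 h (adjusted p = 0.646 and 0.951) and of plasminogen, sterol and stress genes at 48 h (0.706, 0.00391 and 0.919), and held 0 of 6 and 9 of 15 calls. It held 4 of 4 calls for time in MCF7, 6 of 7 in MDA-MB-231 and 7 of 9 in the vehicle comparison, where Wnt genes (0.111) and luminal markers (0.0591) no longer passed. NF-kB and interferon-stimulated genes in the 48 h line difference, retinoic acid-induced and DNA replication genes for time in MCF7, and retinoic acid-induced and NF-kB genes for time in MDA-MB-231 held with the slide block and under the 6 signals and scalings. Lists for differences were not tested with outlier-marked spots kept or on genes measured on both arrays. Those settings had turned some lists in MCF7 at 6 h.

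Of 130 named calls, 104 held with the replicate block, 109 without background correction, 119 with no filter, 72 under scale normalization, 72 in the authors' table, 51 with outlier-marked spots kept, 28 with the stricter filter (95 not measured there), 20 under the log10 ratio, 4 under median centring, 1 under the processed signals and 31 to 108 without 1 array. No named call that was still measured changed sign under these settings. The 95 not measured with the stricter filter could not, nor could calls on MCF7 6 h replicate 1 alone once that array was left out. Calls of retinoic acid against vehicle on both arrays had the same sign on each (84 of 84, 58 of 58, 11 of 11 and 150 of 150 by group). Leaving out 1 array thus could not turn them. Named genes were not run with slide blocks, the intensity trend, array weights, fits to the compared arrays alone or the mean of probes. Signal over background limited MCF7 6 h replicate 2 most, where 37.5% of spots were outlier-marked, and the genes measured on 1 array of that group rest mostly on replicate 1.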

Other observations

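All tests of explanations in this part were chosen after the results were seen, and the comparison of vehicle levels between times was added then too.

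Vehicle-treated cultures themselves differed between 48 and 6 h. In MCF7, vehicle CYP26A1 stood at -4.16 log2 units (48 h minus 6 h, adjusted p = 0.00328), P2RY6 at -2.67 (0.00397), TNFAIP2 at -1.61 (0.00492), the imprinted RNA H19 at -1.55 (0.00849) and APOA1 at -1.15 (0.0301), while the activin inhibitor FST (1.84, 0.00648) and TGFBI (1.49, 0.0166) were higher. The receptor RARG (1.13, 0.0149) was higher too. CYP26A1, P2RY6, H19, TGFBI and RARG were measured on 1 of the 6 h arrays, and TGFBI on 1 of the 48 h arrays. In all, 2592 of 23548 genes passed, 1935 higher and 657 lower at 48 h.

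In MDA-MB-231, the reductase DHRS3 was higher at 48 h by 2.72 (adjusted p = 0.00995), the cyclin-dependent kinase inhibitor CDKN1C by 2.20 (0.00358), the translation inhibitor PDCD4 by 2.05 (0.00257), the cystatin CST1 by 1.94 (0.0101), the tissue plasminogen activator PLAT by 1.86 (0.00321), ICAM1 by 1.55 (0.00525) and IL1B by 1.24 (0.00446). The cyclin CCND1 (-1.60, 0.00499) and the matrix protein THBS1 (-1.71, 0.00446) were lower. In all, 4305 of 23548 genes passed, 2685 higher and 1620 lower. The fits of these 2 comparisons, of at most 2 arrays with 2 in each line, did not part time in culture, slide and array. For CYP26A1, P2RY6, H19, TGFBI and RARG in MCF7, all arrays measured were on slide 1, so slide did not differ. The MDA-MB-231 genes named above kept their direction on 48 h replicate 1, which shared slide 2 with both 6 h arrays. Time in culture and array remain unparted.

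Genes raised by retinoic acid in MDA-MB-231 at 48 h stood lower in vehicle-treated cells of that line at 6 h than at 48 h, by a median of -0.55 log2 units over 97 genes, and the list of genes widely described as retinoic acid-induced by -0.33 (percentile 0.49 of matched random lists). Both lines were looked at, and the pattern first looked for, in MCF7, did not hold: the genes raised there at 6 h stood at -0.13 (percentile 7.93) and the list at -0.01 (percentile 74.9). The MCF7 values use replicate 1 as the only 6 h array, while those of MDA-MB-231 use both 6 h arrays. Bleed of the retinoic acid channel into the vehicle channel is argued against as the whole source, since taking off the largest bleed that the arrays allow left -0.36, below all of 10000 matched lists (their median 0.02). A difference between slides is argued against too, since against 48 h replicate 1, on the slide of both 6 h arrays, the value was -0.62 (98 genes, matched lists -0.05), and against replicate 2 it was -0.52. What lies behind the pattern stays open. RARB, CYP26A1 and RARRES1, which retinoic acid raised in this line at 48 h, stood at 0.10, 0.09 and 0.13 in vehicle-treated cells (48 h minus 6 h, adjusted p = 0.761, 0.796 and 0.509), with CYP26A1 near background. The medium, its serum and the density of the cells were not tested.

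HOX genes rose as a list in MCF7 at 6 h, and the hypothesis that genes nearer the 3 prime end of a cluster (low paralog numbers) rise more was tested. The Spearman correlation of paralog number with log2 ratio was -0.22 over 29 genes (Pearson -0.23, permutation p = 0.250), which leaves the question open.

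Where the lower channel lay at background and the ratio was turned into a bound, MDA-MB-231 at 48 h had 171 genes bounded downward, against 4 to 12 in each direction of the other groups and 4 upward in the same group. These genes were counted by signal over background alone, without a test of the change. In that comparison 54 genes were called lower, so most of the 171 were not called.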
